A study of Gossypium hirsutum with 18 samples.

How the data were processed

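Root and leaf RNA of cotton seedlings was measured in 18 libraries, 3 from each of 6 groups, and groups were taken from the sample labels. Nothing in the labels says whether the 3 libraries of a group came from separate plants, so every p-value here measures only the spread between these libraries, which can be technical. Libraries were made from poly(A) RNA and read as pairs on an Illumina HiSeq instrument, per the labels' protocols, and the strandedness of the libraries is not stated. The submitters' processing notes name HISAT for alignment and StringTie for quantification, without versions.

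The deposited table lists 70478 genes with whole-number counts, which the authors did not normalize, and with FPKM values, fragments scaled by gene length and library total, that the authors computed, per the file headers. Each of 302270 values with a count of 0 is listed at an FPKM floor of 0.0001. Among counts from 1 to 20, between 56.1% and 59.8% per library were even, an excess of even numbers such as arises when both reads of a pair are counted, so counting error is larger than the counts alone give. Gene names are the deposited descriptions, which 58015 genes carry. Of the gene identifiers, 0 matched the reference table of 99454 genes (assembly Gossypium_hirsutum_v2.1), so no names were taken from it. Upland cotton is an allotetraploid, and how reads shared between A and D copies of a gene were assigned is not stated, so values of such pairs are uncertain.

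Total counts per library were 46345805, 55553228 and 53836714 in CK roots, 62836133, 66557277 and 53608937 in AS roots and 52706676, 56239343 and 56133704 in SAS roots. In leaves they were 54430372, 65822432 and 64337165 in CK, 66843791, 58072982 and 54634625 in AS and 57133798, 52753477 and 59105653 in SAS. A gene at 0 counts in every library of a group was set to a floor of 3 counts per library, and its fold is given as a lower bound. Its fitted log2 value depends on the prior count and is printed only for differences between root and leaf responses, beside their bound. Floors cover counting error only.

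The test first planned was limma on log2(FPKM + 1). After the table proved to hold counts, edgeR's quasi-likelihood test on the counts was made the main test, and the limma test was kept as an alternative. Each tissue was fitted over its 9 libraries with TMM scaling, for genes with an FPKM of at least 1 in at least 3 of them, which left 39584 genes in root and 44761 in leaf. P-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called. Levels of single genes are CPM, the count divided by the library total times its TMM factor and multiplied by 1e6. The standard error of a log2 change is its size divided by the square root of the F statistic. The biological coefficient of variation was 0.290 in root and 0.197 in leaf. Differences between root and leaf responses were tested as interaction terms in a fit of all 18 libraries, over 35697 genes. Agreement of the AS and SAS responses was measured as correlation and covariance across genes, beside simulations with no treatment effect and the same controls.

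The 38 gene lists were chosen before the data were examined, as were the comparisons, the rule for naming genes and the alternatives not marked below as added. Their members were matched to the deposited descriptions, and the match was revised from the descriptions before any test. Of 207 pairs of list and comparison tested both ways, 26 had another call with the lists as first written, and 18 further pairs were too small to test as first written. Passed only as first written were abscisic acid genes (AS roots, SAS roots), alternative oxidases and dehydrogenases (AS leaves), clock genes (SAS against AS in leaves), ethylene genes (AS leaves, AS roots), phenylpropanoid genes (AS leaves) and sodium and potassium genes (SAS leaves). Passed only as revised were alternative oxidases and dehydrogenases (SAS against AS in leaves), cell division genes (AS leaves, SAS leaves), clock genes (AS roots), ethylene genes (SAS leaves, SAS roots), flavonoid genes (SAS roots), heat shock genes (AS leaves), organelle-type transcripts (SAS against AS in leaves), anion efflux genes (SAS against AS in leaves), phenylpropanoid genes (AS roots, SAS against AS in roots), ribosomal protein genes (SAS against AS in leaves, SAS against AS in roots, SAS leaves, SAS roots), root markers (SAS roots) and sulfate genes (SAS against AS in leaves). Root markers in leaves were tested only as first written, over 63 genes, and passed upward in SAS against CK (camera adjusted p = 1.7e-04) and SAS against AS (camera adjusted p = 3.4e-04). Lists were tested with camera, two-sided, with a preset correlation of 0.01 and, beside it, with a correlation estimated from the residuals, for lists of at least 5 tested genes. GO and KEGG terms of 15 to 500 tested genes were tested in the same way. With genes at 0 counts in a group set to their bound, the median log2 change moved from 0.12 to 0.00 for late embryogenesis abundant proteins and dehydrins (AS against CK in roots), from 0.90 to 0.89 for fermentation and low oxygen (AS against CK in roots) and from -0.12 to -0.08 for class III peroxidases (SAS against AS in roots), and by less than the rounding for the other lists.

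Named genes follow a rule. For each comparison it takes the 5 genes with the highest and the 5 with the lowest log2 change, and up to 3 members with the largest change from each list that passed camera. All must have an adjusted p under 0.05, no overlap between the libraries of both groups, a mean FPKM of at least 10 in the higher group and a description that names a product. For each interaction it takes the 5 genes with the largest difference. The text prints a selection of the genes that the rule took.

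The methods were tested on simulated counts with 200 changed genes. In the root comparison of AS and CK, edgeR found 9 of 100 genes changed by 2-fold and 73 of 100 changed by 4-fold, and called 4 unchanged genes. In leaf these counts were 52, 90 and 17. Camera called 0 of 20 unchanged lists, which leaves correlation in real lists untested. Alternatives fixed beforehand were limma on log2 FPKM with pseudocounts of 1 and 0.1, no filter or an FPKM minimum of 5, median-ratio scaling, fits of all 18 or only the 6 compared libraries, the replicate number as a block, and each library left out in turn. DESeq2, library totals as the only scaling, a fixed replicate term for the interactions and the estimated correlation for annotation terms were added after the data were seen. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9, with data.table in version 1.17.8.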

Results

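Poly(A) RNA was sequenced as read pairs from roots and leaves of upland cotton (Gossypium hirsutum) seedlings that had been raised in soil and moved into a treatment solution. The labels name 125 mM NaHCO3 and NaOH of matching pH as the solutions, each applied for 12 h, and code the treated libraries AS or SAS. They do not say which code stands for which solution, so both codes are kept here as given. The labels list CK as without treatment and give neither its solution nor its time of sampling, so changes against CK can include effects of the move into solution or of sampling time. Each of the 6 groups, CK, AS and SAS in root and in leaf, had 3 libraries, and total counts ran from 46345805 to 66843791 per library. The stated purpose of the series was to follow transcripts, among them those for removal of reactive oxygen species, under both kinds of alkaline stress. Values for single genes below are scaled counts (CPM, defined with the processing), as mean ± SD over n = 3 libraries, and ± after a log2 change is its standard error. In each comparison where a gene is named as changed, the 3 libraries of one group all lay above the 3 of the other, which chance gives for 10% of unchanged genes.

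Both tissues separated by treatment. The leading principal component held 61.9% of the variance in roots, with CK libraries at -212 to -178, AS at 8.72 to 22.3 and SAS at 177 to 185, and 63.1% in leaves, with CK at -128 to -106, AS at -33.0 to 0.491 and SAS at 91.3 to 183. In roots 15044 of 39584 genes changed in AS and 22551 in SAS, and in leaves 9268 of 44761 in AS and 23805 in SAS. Median log2 changes over all tested genes stayed between -0.06 and 0.00 with the scaling used here. With library totals as the only scaling they shifted by -0.48 in AS roots and -0.54 in SAS roots, so changes in roots are relative to the typical gene. The deposited gene coordinates, whose genome build is not given in the sources used here, place alternative oxidase 1A, Gh_D12G2621, on chromosome D12 from 58992715 to 58993988, ATP sulfurylase 1, Gh_D02G0399, on chromosome D02 from 5159808 to 5161716, and senescence-associated gene 12, Gh_D06G1428, on chromosome D06 from 46113687 to 46114499.

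**Figure D1:**
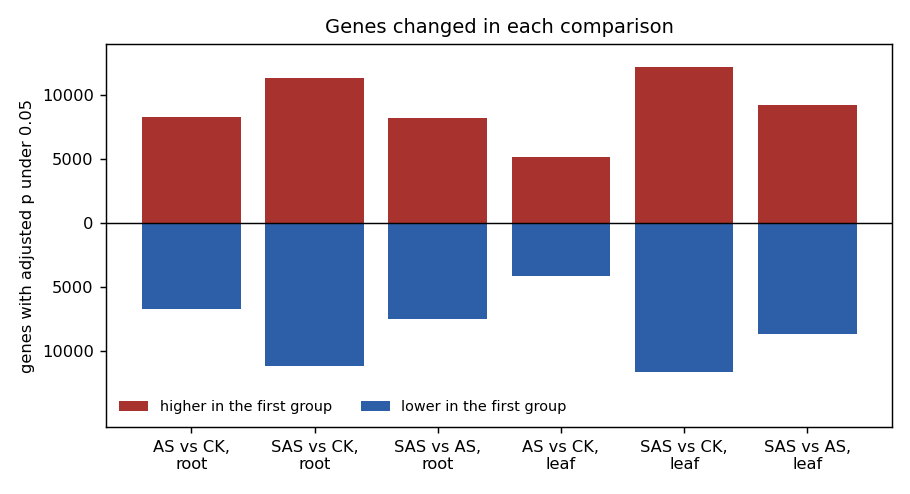
Number of genes with an adjusted p under 0.05 in each comparison, higher above 0 and lower below 0, from edgeR's quasi-likelihood test on 3 libraries per group. SAS against CK gave the most genes in each tissue, 22551 in roots and 23805 in leaves.

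AS against CK in roots asks what alkaline treatment AS did to root transcripts. Genes of the mitochondrial respiratory bypass were among those that rose: alternative oxidase 1A, Gh_D12G2621, which passes electrons from ubiquinol to oxygen without pumping protons, went from 23.01 ± 7.41 CPM to 404 ± 40.6 (log2 4.13 ± 0.32, adjusted p = 2.9e-05), and the external NAD(P)H dehydrogenase B2, Gh_A06G1090, went from 5.11 ± 0.992 to 121 ± 29.7 (log2 4.57 ± 0.27, adjusted p = 1.2e-05). SPX domain gene 2, Gh_D10G0726, of the phosphate-sensing family was at 0 counts in CK roots and at least 230.2-fold higher in AS roots (adjusted p = 0.00122). Sulfate transporter 4;2, Gh_D10G2162, which releases sulfate from the vacuole, rose from 23.7 ± 2.90 to 162 ± 30.01 (log2 2.77 ± 0.21, adjusted p = 2.9e-05). At the other end, osmotin 34, Gh_D12G2246, a pathogenesis-related protein, fell from 193 ± 110.0 to 2.67 ± 1.43 (log2 -6.18 ± 0.60, adjusted p = 9.3e-05). Cinnamate-4-hydroxylase, Gh_A10G1590, an early enzyme of the phenylpropanoid pathway, fell from 161 ± 23.1 to 24.7 ± 9.82 (log2 -2.71 ± 0.28, adjusted p = 1.3e-04).

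Among 16 alternative oxidases and type II NAD(P)H dehydrogenases, 10 rose and 2 fell, with 10 and 3 adjusted over the list alone. Alternative oxidases and dehydrogenases had a median log2 change of 1.82 (camera adjusted p = 8.1e-11, adjusted p = 0.0116 with an estimated correlation). For the 210 heat shock proteins and heat shock factors, 117 rose and 15 fell, or 140 in all adjusted over the list alone. As a group they had a median log2 change of 0.96 (camera adjusted p = 1.3e-22, adjusted p = 0.173 with an estimated correlation). Mitochondrial small heat shock protein 23.6, Gh_D12G1971, rose from 0.746 ± 0.305 to 186 ± 62.8 (log2 7.95 ± 0.44, adjusted p = 9.6e-06). Of 35 measured genes for compatible solutes and stress sugars, 25 rose and 3 fell, or the same counts adjusted over the list alone. Compatible solute genes had a median log2 change of 1.74 (camera adjusted p = 4.2e-10, adjusted p = 0.191 with an estimated correlation). Galactinol synthase 1, Gh_A11G0980, which starts the raffinose family of sugars, rose from 5.89 ± 2.11 to 148 ± 51.5 CPM. Among 39 sulfate assimilation genes, 23 rose and 5 fell, with the same counts adjusted over the list alone. The list's median log2 change was 1.30 (camera adjusted p = 5.1e-06, adjusted p = 0.371 with an estimated correlation). For the 79 phosphate starvation genes, 32 rose and 6 fell, or 35 and 10 adjusted over the list alone. Phosphate genes had a median log2 change of 0.42 (camera adjusted p = 0.0190, adjusted p = 0.657 with an estimated correlation), although the median was -0.05 with library totals as the only scaling, where 28 were higher and 24 lower. Purple acid phosphatase 10, Gh_D13G0308, which frees phosphate from organic forms, rose from 4.80 ± 4.20 to 156 ± 44.0 CPM (log2 5.02, 5.84 without CK root library 3). Of 149 measured NAC transcription factors, 64 rose and 19 fell, or 68 and 24 adjusted over the list alone. On the log2 scale their median change was 0.53 (camera adjusted p = 2.3e-06, adjusted p = 0.0820 with an estimated correlation).

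Among 98 glutathione S-transferases, which join glutathione to reactive molecules, 37 rose and 19 fell, with 39 and 21 adjusted over the list alone. Glutathione S-transferases had a median log2 change of 0.33 (camera adjusted p = 0.00831, adjusted p = 0.371 with an estimated correlation), although the median was -0.15 with library totals as the only scaling, where 27 were higher and 34 lower. Against that, the list's share of all counts went from 0.583% ± 0.0658 (SD) in CK to 0.568% ± 0.104 in AS. Glutathione S-transferase TAU 19, Gh_D13G1617, rose from 1.40 ± 0.550 to 36.5 ± 5.30 (log2 4.70 ± 0.36, adjusted p = 2.9e-05). For the 49 genes of fermentation and low oxygen, 22 rose and 1 fell, or 25 and 1 adjusted over the list alone. The members' median log2 change was 0.90, or 0.89 with genes at 0 counts set to their bound (camera adjusted p = 3.5e-05, adjusted p = 0.371 with an estimated correlation). Sucrose synthase 4, Gh_D05G0363, rose from 292 ± 30.2 to 852 ± 143 CPM. Of 46 measured photosystem and light harvesting genes, 16 rose and 1 fell, or the same counts adjusted over the list alone. Photosystem genes had a median log2 change of 0.75 (camera adjusted p = 0.0190, adjusted p = 0.513 with an estimated correlation). A chlorophyll a/b-binding protein gene, Gh_D09G2122, went from 1.92 ± 1.14 to 31.6 ± 10.6 CPM, and the share of counts from organelle-type transcripts was 0.00220% ± 4.2e-04 (SD) in AS roots against 0.00129% ± 1.6e-04 in CK roots. Among 46 circadian clock genes, 19 rose and 1 fell, with 20 and 3 adjusted over the list alone. Across the list the median log2 change was 0.42 (camera adjusted p = 0.00846, adjusted p = 0.439 with an estimated correlation, and 0.856 by camera for the list as first written), although the median was -0.06 with library totals as the only scaling, where 11 were higher and 12 lower. Pseudo-response regulator 5, Gh_A11G0142, a clock repressor, rose from 0.462 ± 0.491 to 23.95 ± 3.07 CPM (log2 5.69, 7.05 without CK root library 3).

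For the 89 class III peroxidases, secreted enzymes that act on hydrogen peroxide and phenolics, 11 rose and 44 fell, or the same counts adjusted over the list alone. Peroxidases had a median log2 change of -1.48 (camera adjusted p = 1.4e-06, adjusted p = 0.371 with an estimated correlation). Root hair and endodermis markers, which did not pass camera (adjusted p = 0.136), had a median log2 change of -0.33, and their share of counts went from 0.0275% ± 0.00164 (SD) in CK to 0.00786% ± 0.00191 in AS roots. One peroxidase, Gh_D12G0853, fell from 14.6 ± 9.91 to 0.269 ± 0.257 (log2 -5.74 ± 0.83, adjusted p = 7.4e-04, log2 -5.08 without CK root library 2, log2 -6.90 without AS root library 2), while peroxidase 2, Gh_D11G2183, rose from 0.653 ± 0.459 to 30.6 ± 4.33 CPM (log2 5.54, 6.26 without CK root library 2). Of 80 measured phenylpropanoid and lignin genes, 14 rose and 41 fell, or 15 and 45 adjusted over the list alone. Together they had a median log2 change of -1.13 (camera adjusted p = 5.4e-05, adjusted p = 0.371 with an estimated correlation, and 0.832, upward, by camera for the list as first written). Among 30 flavonoid synthesis genes, 2 rose and 18 fell, with 3 and 18 adjusted over the list alone. Flavonoid genes had a median log2 change of -1.40 (camera adjusted p = 1.1e-04, adjusted p = 0.523 with an estimated correlation). For the 45 genes of sesquiterpene synthesis, the route to gossypol, 9 rose and 24 fell, or 10 and 25 adjusted over the list alone. Their median log2 change was -1.18 (camera adjusted p = 0.00224, adjusted p = 0.555 with an estimated correlation). Terpene synthase 21, Gh_D05G3507, fell from 886 ± 177 to 111 ± 82.1 CPM (log2 -2.998, -3.78 without AS root library 3). Hydroxymethylglutaryl-CoA reductase 1, Gh_A12G0103, the regulated step of the mevalonate pathway, fell from 78.6 ± 19.8 to 11.4 ± 6.71 CPM (log2 -2.79, -3.38 without AS root library 3). Of 62 measured aquaporins, 12 rose and 18 fell, or 12 and 19 adjusted over the list alone. Aquaporins had a median log2 change of -0.82 (camera adjusted p = 0.0363, adjusted p = 0.513 with an estimated correlation). Among these, plasma membrane intrinsic protein 1;4, Gh_D10G2359, fell from 62.6 ± 22.9 to 10.7 ± 5.02 CPM, while a gamma tonoplast intrinsic protein, Gh_D04G1049, rose from 27.8 ± 10.5 to 132 ± 27.1 CPM.

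Of 39584 genes, 8311 were higher and 6733 lower in AS than in CK roots, 9839 of them by at least 2-fold, and 16 of 38 gene lists passed camera, 11 upward and 5 downward. WRKY factors also passed upward, with a median log2 change of 0.31, or -0.16 with library totals as the only scaling. With an estimated correlation 1 list passed, the alternative oxidases and dehydrogenases. Of the changed genes 55.2% were higher, against 24.4% with library totals as the only scaling and 22.7% with limma on log2 FPKM.

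SAS against CK in roots puts the same question to treatment SAS. Alternative oxidase 1A, Gh_D12G2621, rose from 23.01 ± 7.41 to 2414 ± 396 (log2 6.71 ± 0.36, adjusted p = 1.2e-06). Several genes at 0 counts in CK roots were strongly expressed: SPX domain gene 2, Gh_D10G0726, was at least 1451-fold higher (adjusted p = 1.7e-04, or 920.1-fold without SAS root library 3), UDP-glucosyl transferase 85A2, Gh_D13G0523, at least 1394-fold higher (adjusted p = 1.1e-04), and a pyruvate decarboxylase, Gh_D08G0005, at least 1157-fold higher (adjusted p = 4.7e-04). Jasmonate-zim-domain protein 8, Gh_D09G0743, a repressor of jasmonate signalling, was also at 0 counts in CK roots and at least 1139.8-fold higher (adjusted p = 8.4e-06). ACC synthase 1, Gh_A11G0831, which makes the precursor of ethylene, rose from 0.294 ± 0.133 to 162 ± 29.8 (log2 9.08 ± 0.36, adjusted p = 5.2e-07). Respiratory burst oxidase homologue D, Gh_A05G1666, an NADPH oxidase that makes superoxide, rose from 5.01 ± 1.11 to 102 ± 20.1 (log2 4.35 ± 0.23, adjusted p = 1.2e-06). Osmotin 34, Gh_D12G2246, fell from 193 ± 110.0 to 0.600 ± 0.119 (log2 -8.33 ± 0.67, adjusted p = 9.8e-06). A SOUL heme-binding protein, Gh_D02G1632, fell from 11.2 ± 7.10 to 0.0478 ± 0.0827 (log2 -7.78 ± 0.99, adjusted p = 1.4e-04, SAS root libraries other than 2 at 0 counts).

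Among 149 NAC transcription factors, 93 rose and 13 fell, with 93 and 14 adjusted over the list alone. As a group they had a median log2 change of 1.31 (camera adjusted p = 3.7e-11, adjusted p = 0.0234 with an estimated correlation). WRKY transcription factors numbered 115 that rose, 39 that fell and 46 that did not pass, or 116 and 40 that passed upward and downward when adjusted over the list alone. WRKY factors had a median log2 change of 1.13 (camera adjusted p = 3.1e-07, adjusted p = 0.319 with an estimated correlation). WRKY40, Gh_D05G1137, rose from 2.97 ± 1.60 to 308 ± 129 CPM. Of 75 measured jasmonate genes, 46 rose and 6 fell, or 46 and 7 adjusted over the list alone. The list's median log2 change was 1.71 (camera adjusted p = 3.5e-08, adjusted p = 0.242 with an estimated correlation). Against that, the list's share of all counts went from 1.33% ± 0.146 (SD) in CK to 1.14% ± 0.00812 in SAS. Among 157 ethylene synthesis and response genes, 84 rose and 35 fell, with 85 and 36 adjusted over the list alone. Ethylene genes had a median log2 change of 0.84 (camera adjusted p = 4.1e-06, adjusted p = 0.176 with an estimated correlation, and 0.836 by camera for the list as first written). The ethylene share of all counts, with the same shift, went from 1.04% ± 0.0541 (SD) in CK to 0.953% ± 0.0603 in SAS. As first written the ethylene list passed downward in AS roots (camera adjusted p = 0.00444) and AS leaves (camera adjusted p = 0.00945). Ethylene-responsive element binding factor 13, Gh_A11G0685, was at 0 counts in CK roots and at least 605-fold higher in SAS roots (adjusted p = 1.7e-05). For the 14 NADPH oxidases, 8 rose and 0 fell, or the same counts adjusted over the list alone. On the log2 scale their median change was 1.49 (camera adjusted p = 6.5e-05, adjusted p = 0.174 with an estimated correlation). Of 16 measured alternative oxidases and dehydrogenases, 10 rose and 2 fell, or the same counts adjusted over the list alone. Alternative oxidases and dehydrogenases had a median log2 change of 1.87 (camera adjusted p = 7.1e-09, adjusted p = 0.0221 with an estimated correlation). Among 50 senescence and chlorophyll breakdown genes, 33 rose and 8 fell, with 35 and 8 adjusted over the list alone. The members' median log2 change was 1.44 (camera adjusted p = 6.0e-04, adjusted p = 0.0490 with an estimated correlation). Senescence-related gene 1, Gh_A10G0299, rose from 6.51 ± 3.61 to 625 ± 291 CPM, while senescence-associated gene 21, Gh_A10G1465, fell from 289 ± 124.8 to 36.1 ± 15.4 CPM.

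For the 39 sulfate assimilation genes, 28 rose and 4 fell, or the same counts adjusted over the list alone. Sulfate genes had a median log2 change of 2.67 (camera adjusted p = 1.1e-10, adjusted p = 0.125 with an estimated correlation). Serine acetyltransferase 2;2, Gh_D13G1404, which makes the precursor of cysteine, rose from 0.242 ± 0.163 to 40.7 ± 12.9 (log2 7.40 ± 0.47, adjusted p = 2.5e-06, log2 8.05 without CK root library 1). Of 45 measured nitrate and ammonium genes, 28 rose and 1 fell, or the same counts adjusted over the list alone. Across the list the median log2 change was 1.31 (camera adjusted p = 0.00122, adjusted p = 0.319 with an estimated correlation). Nitrate transporter 1.5, Gh_A13G0105, rose from 0.143 ± 0.185 to 72.3 ± 26.7 CPM (log2 8.92, 10.75 without CK root library 2). Heat shock factor A3, Gh_A09G2455, rose from 0.973 ± 0.157 to 117 ± 35.6 CPM. Among 46 photosystem and light harvesting genes, 22 rose and 2 fell, with the same counts adjusted over the list alone. Photosystem genes had a median log2 change of 1.08 (camera adjusted p = 0.0164, adjusted p = 0.440 with an estimated correlation). All 8 organelle-type transcripts, the RNA quality check, rose, also adjusted over the list alone. Their median log2 change was 3.40 (camera adjusted p = 0.00430, adjusted p = 0.463 with an estimated correlation). Their share of counts was 0.00600% ± 0.00293 (SD) in SAS and 0.00129% ± 1.6e-04 in CK roots, so RNA quality may differ.

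Of 89 measured class III peroxidases, 20 rose and 52 fell, or 20 and 54 adjusted over the list alone. Peroxidases had a median log2 change of -2.10 (camera adjusted p = 5.8e-04, adjusted p = 0.440 with an estimated correlation). Among 7 root hair and endodermis markers, 1 rose and 3 fell, with the same counts adjusted over the list alone. Their median log2 change was -0.30 (camera adjusted p = 0.0164, adjusted p = 0.174 with an estimated correlation, and 0.0806, upward, by camera for the list as first written). Their share of counts was 0.00453% ± 1.4e-04 (SD) in SAS roots. Root hair specific 19, Gh_D03G0246, fell from 22.1 ± 4.81 to 0.875 ± 0.506 (log2 -4.65 ± 0.45, adjusted p = 2.8e-05). For the 620 cytosolic ribosomal protein genes, 73 rose and 194 fell, or 63 and 173 adjusted over the list alone. Ribosomal protein genes had a median log2 change of -0.24 (camera adjusted p = 0.0368, adjusted p = 0.883 with an estimated correlation, and 0.283 by camera for the list as first written). An exception was a ribosomal protein L19e gene, Gh_A03G0797, which rose from 1.45 ± 0.664 to 631 ± 83.1 CPM.

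Of 39584 genes, 11330 were higher and 11221 lower in SAS than in CK roots, 15978 of them by at least 2-fold, and 18 of 38 gene lists passed camera, 14 upward and 4 downward. Glutathione S-transferases, heat shock and compatible solute genes also passed upward and flavonoid genes downward. With an estimated correlation 3 lists passed, the alternative oxidases and dehydrogenases, NAC factors and senescence genes. The share of changed genes that were higher was 50.2%, against 28.6% with library totals as the only scaling and 28.3% with limma on log2 FPKM.

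SAS against AS in roots tests where both treatments differed. Allene oxide cyclase 4, Gh_D08G0414, of jasmonate synthesis, was higher in SAS, at 17.98 ± 7.84 CPM in AS and 263 ± 49.4 in SAS (log2 3.87 ± 0.54, adjusted p = 7.2e-04). Tonoplast intrinsic protein 4;1, Gh_D06G0982, a water channel, rose from 1.15 ± 0.626 to 80.3 ± 34.9 (log2 6.11 ± 0.58, adjusted p = 1.6e-04). Alcohol dehydrogenase 1, Gh_D11G0605, of ethanol fermentation, was lower in SAS and went from 23.995 ± 6.69 to 1.77 ± 1.15 (log2 -3.76 ± 0.54, adjusted p = 7.7e-04). A lipid-transfer protein, Gh_D10G2502, fell from 142 ± 74.2 to 1.01 ± 1.41 (log2 -7.13 ± 1.30, adjusted p = 0.00241, log2 -9.44 without SAS root library 2).

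Of 75 measured jasmonate genes, 53 were higher in SAS and 2 lower, or 57 and 3 adjusted over the list alone. As a group they had a median log2 change of 1.67 (camera adjusted p = 1.5e-15, adjusted p = 0.124 with an estimated correlation). Against that, the list's share of all counts went from 1.19% ± 0.153 (SD) in AS to 1.14% ± 0.00812 in SAS. Among 157 ethylene genes, 94 were higher and 11 lower, with 96 and 12 adjusted over the list alone. Ethylene genes had a median log2 change of 1.10 (camera adjusted p = 3.8e-13, adjusted p = 0.0698 with an estimated correlation). For the 45 sesquiterpene genes, 28 were higher and 1 lower, or 33 and 2 adjusted over the list alone. The list's median log2 change was 1.30 (camera adjusted p = 4.4e-09, adjusted p = 0.287 with an estimated correlation). Hydroxymethylglutaryl-CoA reductase 1, Gh_A12G0103, went from 11.4 ± 6.71 to 81.6 ± 23.04 CPM. Of 14 measured NADPH oxidases, 11 were higher and 0 lower, or 12 and 0 adjusted over the list alone. NADPH oxidases had a median log2 change of 1.58 (camera adjusted p = 4.3e-08, adjusted p = 0.0698 with an estimated correlation). Among 39 sulfate genes, 29 were higher and 3 lower, with 30 and 3 adjusted over the list alone. On the log2 scale their median change was 1.33 (camera adjusted p = 1.3e-07, adjusted p = 0.241 with an estimated correlation). For the 49 fermentation and low-oxygen genes, 11 were higher and 21 lower, or the same counts adjusted over the list alone. Low-oxygen genes had a median log2 change of -0.68 (camera adjusted p = 0.00935, adjusted p = 0.579 with an estimated correlation). A pyruvate decarboxylase, Gh_D08G0005, went against them, from 3.44 ± 4.63 to 53.7 ± 24.8 CPM (log2 3.96, 6.12 without AS root library 1).

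Of 39584 genes, 8195 were higher and 7508 lower in SAS than in AS roots, 10082 of them by at least 2-fold, and 16 of 38 gene lists passed camera, 13 upward and 3 downward. The other lists higher in SAS were glutathione S-transferases, alternative oxidases, nitrate, WRKY, NAC, phenylpropanoid, senescence and organelle-type genes, and the other lists lower were ribosomal and circadian genes, while the phenylpropanoid share of all counts went from 1.08% ± 0.130 (SD) in AS to 0.960% ± 0.0569 in SAS. With an estimated correlation 0 of these 16 lists passed camera, and 7 lists had an unadjusted p under 0.05, the lowest adjusted p being 0.0698.

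**Figure D2:**
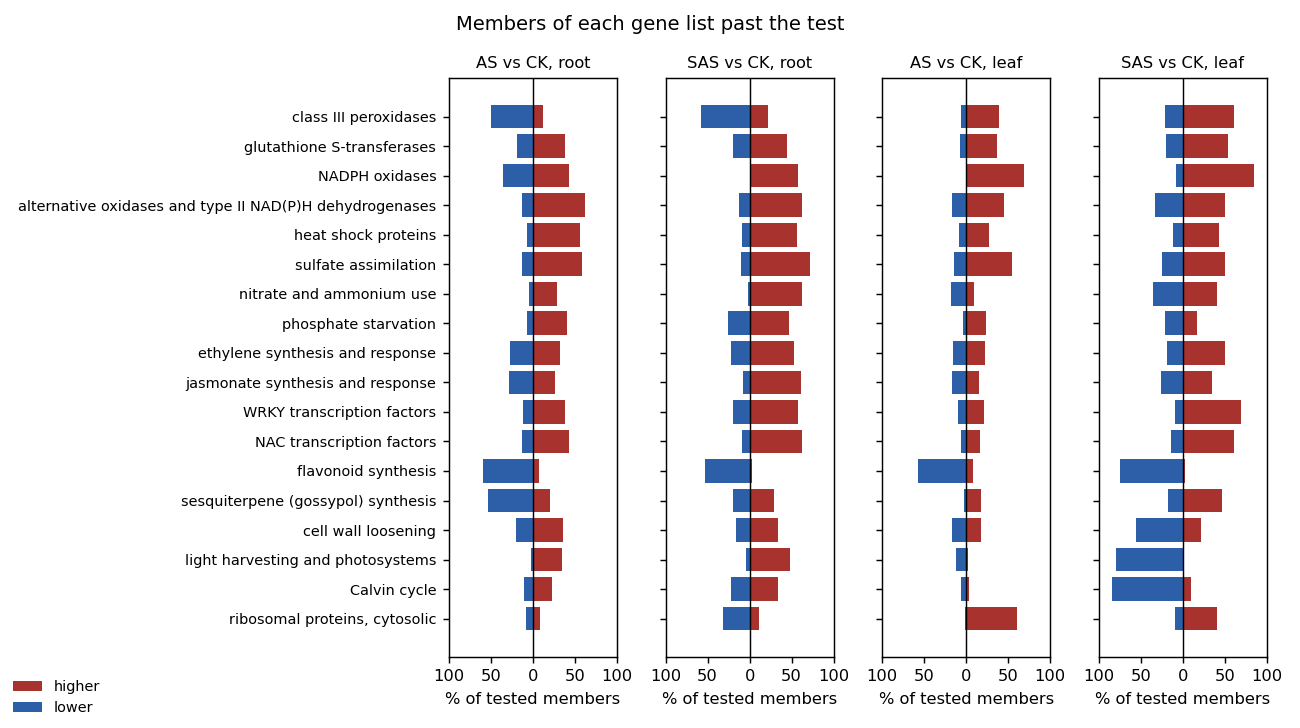
Share of the tested members of 18 gene lists that were higher, to the right, or lower, to the left, at an adjusted p under 0.05 in AS or SAS against CK, in roots and in leaves, 3 libraries per group. In SAS leaves 120 of 151 photosystem and light harvesting genes were lower, and for AS roots the medians of glutathione S-transferases, phosphate genes and WRKY factors, above 0 here, were -0.15, -0.05 and -0.16 with library totals as the only scaling.

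AS against CK in leaves asks how leaves responded to treatment AS. ATP sulfurylase 1, Gh_D02G0399, which activates sulfate, rose from 34.9 ± 1.71 to 374 ± 98.2 (log2 3.42 ± 0.19, adjusted p = 8.9e-05). Alcohol dehydrogenase 1, Gh_A01G1605, rose from 4.44 ± 1.81 to 90.1 ± 7.10 (log2 4.34 ± 0.39, adjusted p = 3.0e-04). Phloem protein 2-B15, Gh_D13G1152, rose from 0.0318 ± 0.0550 to 47.1 ± 33.5 (log2 10.37 ± 1.06, adjusted p = 5.3e-04, CK leaf libraries other than 3 at 0 counts). A pectate lyase, Gh_D12G1856, which cuts wall pectin, fell from 92.2 ± 4.11 to 11.4 ± 3.13 (log2 -3.01 ± 0.24, adjusted p = 1.9e-04). Flavanone 3-hydroxylase, Gh_D12G0566, of flavonoid synthesis fell from 1873 ± 133 to 754 ± 56.3 (log2 -1.31 ± 0.19, adjusted p = 0.00190).

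Of 633 measured cytosolic ribosomal protein genes, 386 rose and 9 fell, or 417 and 13 adjusted over the list alone. The members' median log2 change was 0.50 (camera adjusted p = 6.8e-33, adjusted p = 0.0643 with an estimated correlation). Among 40 sulfate assimilation genes, 22 rose and 6 fell, with 24 and 6 adjusted over the list alone. Sulfate genes had a median log2 change of 0.91 (camera adjusted p = 1.7e-17, adjusted p = 0.0643 with an estimated correlation). For the 51 class III peroxidases, 20 rose and 3 fell, or 24 and 5 adjusted over the list alone. Across the list the median log2 change was 0.84 (camera adjusted p = 5.5e-10, adjusted p = 0.0754 with an estimated correlation). Peroxidase 2, Gh_A08G2028, rose from 5.94 ± 1.62 to 100.8 ± 23.6 (log2 4.08 ± 0.28, adjusted p = 1.1e-04). Of 13 measured NADPH oxidases, 9 rose and 0 fell, or 11 and 0 adjusted over the list alone. NADPH oxidases had a median log2 change of 1.24 (camera adjusted p = 4.3e-09, adjusted p = 0.161 with an estimated correlation). Glutathione S-transferases numbered 37 that rose, 7 that fell and 57 that did not pass, or 44 and 9 that passed upward and downward when adjusted over the list alone. Together they had a median log2 change of 0.45 (camera adjusted p = 5.5e-08, adjusted p = 0.0704 with an estimated correlation).

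For the 40 flavonoid genes, 3 rose and 23 fell, or 3 and 24 adjusted over the list alone. Flavonoid genes had a median log2 change of -0.83 (camera adjusted p = 1.2e-09, adjusted p = 0.329 with an estimated correlation). Of 255 measured auxin response genes, 20 rose and 65 fell, or 21 and 80 adjusted over the list alone. Their median log2 change was -0.31 (camera adjusted p = 9.8e-05, adjusted p = 0.221 with an estimated correlation). Among 151 photosystem and light harvesting genes, 3 rose and 19 fell, with 3 and 16 adjusted over the list alone. Photosystem genes had a median log2 change of -0.33 (camera adjusted p = 1.1e-04, adjusted p = 0.824 with an estimated correlation). For the 45 circadian clock genes, the check on time of day of sampling, 2 rose and 10 fell, or 2 and 11 adjusted over the list alone. As a group they had a median log2 change of -0.24 (camera adjusted p = 0.00106, adjusted p = 0.343 with an estimated correlation). Of 106 measured sodium and potassium transport genes, 3 rose and 20 fell, or 3 and 22 adjusted over the list alone. Sodium and potassium genes had a median log2 change of -0.08 (camera adjusted p = 0.0199, adjusted p = 0.212 with an estimated correlation). Among 171 cell division genes, 3 rose and 21 fell, with 2 and 18 adjusted over the list alone. The list's median log2 change was -0.05 (camera adjusted p = 0.0278, adjusted p = 0.824 with an estimated correlation, and 0.0845 by camera for the list as first written), although the median was 0.03 with library totals as the only scaling, where 5 were higher and 16 lower.

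Of 44761 genes, 5144 were higher and 4124 lower in AS than in CK leaves, 2814 of them by at least 2-fold, and 15 of 37 gene lists passed camera, 9 upward and 6 downward. Heat shock, phosphate, fermentation and WRKY genes also passed upward. With an estimated correlation 0 of the 15 lists passed camera, and 7 lists had an unadjusted p under 0.05, the lowest adjusted p being 0.0643. The count of 9268 genes fell to 4149 with root and leaf libraries in a single fit, to 5633, 4639 and 6005 without CK leaf library 1, 2 or 3, and to 4520 and 4830 without AS leaf library 1 or 3, and 55.5% of the genes were higher, against 70.9% with library totals as the only scaling and 68.1% with limma on log2 FPKM.

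SAS against CK in leaves asks the same of treatment SAS. A Rubisco small subunit gene, Gh_D11G1672, fell from 151 ± 34.4 to 36.9 ± 14.6 (log2 -2.03 ± 0.26, adjusted p = 1.8e-04). Photosystem II subunit P-1, Gh_A10G1346, fell from 31.2 ± 4.68 to 6.03 ± 2.22 (log2 -2.37 ± 0.43, adjusted p = 0.00129). Senescence-associated gene 12, Gh_D06G1428, a cysteine protease of ageing leaves, rose from 23.3 ± 11.6 to 992 ± 412 (log2 5.41 ± 0.46, adjusted p = 3.2e-05). Respiratory burst oxidase homolog B, Gh_D11G2743, rose from 0.393 ± 0.193 to 36.0 ± 12.3 (log2 6.53 ± 0.43, adjusted p = 1.4e-05). A UDP-glycosyltransferase, Gh_A12G2647, was at 0 counts in CK leaves and at least 725-fold higher in SAS leaves (adjusted p = 1.9e-04).

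For the 151 photosystem and light harvesting genes, 0 rose and 120 fell, or 130 in all adjusted over the list alone. Photosystem genes had a median log2 change of -1.24 (camera adjusted p = 6.5e-18, adjusted p = 0.392 with an estimated correlation). Of 33 measured Calvin cycle genes, 3 rose and 28 fell, or the same counts adjusted over the list alone. On the log2 scale their median change was -1.14 (camera adjusted p = 1.1e-07, adjusted p = 0.329 with an estimated correlation). Among 40 flavonoid genes, 1 rose and 30 fell, with 2 and 30 adjusted over the list alone. Flavonoid genes had a median log2 change of -1.44 (camera adjusted p = 3.2e-13, adjusted p = 0.270 with an estimated correlation). Leucoanthocyanidin dioxygenase, Gh_D08G1902, of anthocyanin synthesis fell from 1559 ± 105 to 297 ± 109 CPM. For the 96 cellulose synthase and arabinogalactan protein genes, 15 rose and 54 fell, or 16 and 55 adjusted over the list alone. The members' median log2 change was -0.78 (camera adjusted p = 6.5e-06, adjusted p = 0.309 with an estimated correlation). Of 90 measured cell wall loosening genes, 19 rose and 50 fell, or 22 and 53 adjusted over the list alone. Wall loosening genes had a median log2 change of -0.80 (camera adjusted p = 0.00125, adjusted p = 0.282 with an estimated correlation). Expansin A4, Gh_D07G0974, which loosens growing walls, fell from 94.2 ± 16.98 to 11.7 ± 5.38 (log2 -3.01 ± 0.40, adjusted p = 2.2e-04), while expansin-like B1, Gh_D08G1777, rose from 4.55 ± 1.35 to 137 ± 56.7 CPM.

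Among 82 genes of the ascorbate-glutathione cycle, superoxide dismutases and catalases, 17 rose and 35 fell, with 19 and 35 adjusted over the list alone. Across the list the median log2 change was -0.20 (camera adjusted p = 0.0258, adjusted p = 0.432 with an estimated correlation). Ascorbate peroxidase 3, Gh_D01G1632, fell from 22.3 ± 1.33 to 4.56 ± 1.04 (log2 -2.29 ± 0.16, adjusted p = 1.5e-05), while glutathione peroxidase 2, Gh_A09G2408, rose from 2.99 ± 0.713 to 13.1 ± 9.65 CPM (log2 2.12, 1.33 without SAS leaf library 2). For the 183 thioredoxins, glutaredoxins and peroxiredoxins, 29 rose and 72 fell, or the same counts adjusted over the list alone. These redox proteins had a median log2 change of -0.26 (camera adjusted p = 0.0223, adjusted p = 0.392 with an estimated correlation). Of 69 measured organic anion efflux genes, 17 rose and 34 fell, or 17 and 35 adjusted over the list alone. Together they had a median log2 change of -0.50 (camera adjusted p = 0.0128, adjusted p = 0.309 with an estimated correlation).

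Among 184 WRKY transcription factors, 128 rose and 17 fell, with 129 and 21 adjusted over the list alone. WRKY factors had a median log2 change of 1.22 (camera adjusted p = 2.6e-13, adjusted p = 0.270 with an estimated correlation). For the 155 NAC transcription factors, 94 rose and 22 fell, or 96 and 23 adjusted over the list alone. Their median log2 change was 0.74 (camera adjusted p = 2.2e-07, adjusted p = 0.270 with an estimated correlation). Of 13 measured NADPH oxidases, 11 rose and 1 fell, or the same counts adjusted over the list alone. NADPH oxidases had a median log2 change of 2.48 (camera adjusted p = 8.1e-09, adjusted p = 0.270 with an estimated correlation). Among 51 class III peroxidases, 31 rose and 11 fell, with the same counts adjusted over the list alone. As a group they had a median log2 change of 1.51 (camera adjusted p = 1.1e-05, adjusted p = 0.270 with an estimated correlation). Against that, the list's share of all counts went from 0.388% ± 0.0380 (SD) in CK to 0.326% ± 0.0111 in SAS. For the 135 ethylene genes, 68 rose and 26 fell, or 69 and 28 adjusted over the list alone. Ethylene genes had a median log2 change of 0.52 (camera adjusted p = 7.8e-05, adjusted p = 0.309 with an estimated correlation, and 0.704 by camera for the list as first written). Glutathione S-transferases numbered 54 that rose, 20 that fell and 27 that did not pass, or 55 and 22 that passed upward and downward when adjusted over the list alone. The list's median log2 change was 0.70 (camera adjusted p = 7.8e-05, adjusted p = 0.270 with an estimated correlation). Glutathione S-transferase TAU 25, Gh_A13G1329, rose from 0.0421 ± 0.0364 to 42.5 ± 28.4 (log2 9.83 ± 0.90, adjusted p = 4.1e-05). Among 48 senescence and chlorophyll breakdown genes, 26 rose and 9 fell, with the same counts adjusted over the list alone. Senescence genes had a median log2 change of 0.74 (camera adjusted p = 0.00130, adjusted p = 0.282 with an estimated correlation). Non-yellowing 1, Gh_A08G1597, which starts chlorophyll breakdown, rose from 9.12 ± 0.613 to 33.0 ± 9.62 CPM. Alternative oxidase 2, Gh_D04G1513, rose from 10.04 ± 0.0453 to 153 ± 47.4 CPM.

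Of 44761 genes, 12169 were higher and 11636 lower in SAS than in CK leaves, 10676 of them by at least 2-fold, and 23 of 37 gene lists passed camera, 13 upward and 10 downward. Alternative oxidases, sulfate, heat shock, phenylpropanoid, fermentation and ribosomal genes also passed upward, and auxin and cell division genes downward, while the phenylpropanoid share of all counts went from 1.52% ± 0.0227 (SD) in CK to 0.978% ± 0.101 in SAS. With an estimated correlation 0 of the 23 lists passed camera, and 6 lists had an unadjusted p under 0.05, the lowest adjusted p being 0.270.

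SAS against AS in leaves tests where the treatments differed there. A Rubisco small subunit gene, Gh_D07G1759, stood lower in SAS, going from 2712 ± 58.9 to 969.8 ± 329.6 (log2 -1.48 ± 0.23, adjusted p = 0.00147), as did catalase 2, Gh_D03G0021, which removes hydrogen peroxide and went from 434 ± 56.4 to 157 ± 47.6 (log2 -1.47 ± 0.22, adjusted p = 0.00109). Alcohol dehydrogenase 1, Gh_A01G1605, fell from 90.1 ± 7.10 to 0.912 ± 0.578 (log2 -6.61 ± 0.45, adjusted p = 1.5e-04, log2 -7.20 without SAS leaf library 1). Terpene synthase 21, Gh_D01G1963, rose from 28.4 ± 16.4 to 279 ± 214 (log2 3.30 ± 0.57, adjusted p = 0.00215, log2 2.44 without SAS leaf library 2).

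For the 151 photosystem and light harvesting genes, 2 were higher in SAS and 97 lower, or 2 and 109 adjusted over the list alone. On the log2 scale their median change was -0.86 (camera adjusted p = 1.5e-16, adjusted p = 0.461 with an estimated correlation). Of 36 measured organelle-type transcripts, 0 were higher and 7 lower, or 0 and 1 adjusted over the list alone. Organelle-type transcripts had a median log2 change of -0.62 (camera adjusted p = 0.00374, adjusted p = 0.567 with an estimated correlation, and 0.669 by camera for the list as first written). Among 633 cytosolic ribosomal protein genes, 17 were higher and 230 lower, with the same counts adjusted over the list alone. The members' median log2 change was -0.26 (camera adjusted p = 1.8e-07, adjusted p = 0.326 with an estimated correlation, and 0.208 by camera for the list as first written). For the 82 ascorbate-glutathione, superoxide dismutase and catalase genes, 4 were higher and 34 lower, or 4 and 36 adjusted over the list alone. These antioxidant genes had a median log2 change of -0.33 (camera adjusted p = 8.6e-05, adjusted p = 0.326 with an estimated correlation). Of 184 measured WRKY factors, 113 were higher and 7 lower, or 119 and 9 adjusted over the list alone. Across the list the median log2 change was 0.95 (camera adjusted p = 5.1e-15, adjusted p = 0.326 with an estimated correlation). Among 86 phenylpropanoid genes, 39 were higher and 11 lower, with 43 and 12 adjusted over the list alone. Phenylpropanoid genes had a median log2 change of 0.59 (camera adjusted p = 4.0e-04, adjusted p = 0.326 with an estimated correlation).

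Of 44761 genes, 9264 were higher and 8655 lower in SAS than in AS leaves, 6341 of them by at least 2-fold, and 21 of 37 gene lists passed camera, 8 upward and 13 downward. The other lists lower in SAS were Calvin cycle genes, thioredoxins, organic anion efflux, sulfate, flavonoid, cell wall loosening, cellulose, aquaporin and phosphate genes, and the others higher were NADPH oxidases, alternative oxidases, ethylene, NAC, sesquiterpene and senescence genes. With an estimated correlation 0 of the 21 lists passed camera, and 4 lists had an unadjusted p under 0.05, the lowest adjusted p being 0.326, and the gene count fell to 8934, of which 62.0% were higher against 51.7%, with root and leaf libraries in a single fit.

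The lists for proton pumps, organic acid and bicarbonate metabolism, iron uptake, abscisic acid, and late embryogenesis abundant proteins passed camera in none of the 6 comparisons. In SAS roots 25 of 94 proton pump genes rose and 31 fell, or 25 and 31 adjusted over the list alone, and in SAS leaves 23 of 105 rose and 27 fell, or 23 and 26, with median log2 changes of -0.23 against a mean of 0.04 and 0.01 against a mean of -0.13 and a lowest camera adjusted p over the 6 comparisons of 0.124. AS changed 17 upward and 12 downward in roots, or 16 and 12 adjusted over the list alone, and 15 and 3 in leaves, or 13 and 3, and the share of root counts was 0.605% ± 0.0291 (SD) in CK, 0.981% ± 0.0270 in AS and 0.447% ± 0.0717 in SAS. In SAS roots 39 of 132 organic acid and bicarbonate genes rose and 49 fell, or 40 and 50 adjusted over the list alone, and in SAS leaves 43 of 142 rose and 41 fell, or 43 and 42, with median log2 changes of -0.19 against a mean of 0.29 and 0.06 and a lowest camera adjusted p over the 6 comparisons of 0.123. AS changed 28 upward and 28 downward in roots, or 29 and 28 adjusted over the list alone, and 37 and 9 in leaves, or 40 and 12, and the share of root counts was 0.432% ± 0.0228 (SD) in CK, 0.475% ± 0.0455 in AS and 0.451% ± 0.0162 in SAS. In SAS roots 11 of 28 iron uptake genes rose and 5 fell, or 11 and 5 adjusted over the list alone, and in SAS leaves 14 of 36 rose and 10 fell, or 14 and 11, with median log2 changes of 0.37 and 0.24 and a lowest camera adjusted p over the 6 comparisons of 0.203, although the root median was -0.16 with library totals as the only scaling. AS changed 12 upward and 6 downward in roots, or 12 and 6 adjusted over the list alone, and 8 and 4 in leaves, or 8 and 9, and the share of root counts was 0.0808% ± 0.00798 (SD) in CK, 0.131% ± 0.0274 in AS and 0.177% ± 0.0282 in SAS. In SAS roots 24 of 78 abscisic acid genes rose and 22 fell, or 24 and 22 adjusted over the list alone, and in SAS leaves 18 of 90 rose and 20 fell, or 17 and 20, with median log2 changes of -0.07 against a mean of 0.34 and -0.05 against a mean of 0.02 and a lowest camera adjusted p over the 6 comparisons of 0.126. AS changed 21 upward and 18 downward in roots, or 22 and 19 adjusted over the list alone, and 7 and 11 in leaves, or 7 and 11, and the share of root counts was 0.209% ± 0.00446 (SD) in CK, 0.186% ± 0.0164 in AS and 0.159% ± 0.00715 in SAS, and as first written the list passed upward in AS roots (camera adjusted p = 3.8e-05) and SAS roots (camera adjusted p = 0.0242). In SAS roots 7 of 15 late embryogenesis abundant and dehydrin genes rose and 3 fell, or 7 and 3 adjusted over the list alone, and in SAS leaves 8 of 16 rose and 3 fell, or 8 and 3, with median log2 changes of 0.65 and 0.65 and a lowest camera adjusted p over the 6 comparisons of 0.129. AS changed 5 upward and 3 downward in roots, or 5 and 4 adjusted over the list alone, and 2 and 0 in leaves, or 0 and 0, and the share of root counts was 0.0168% ± 0.00107 (SD) in CK, 0.0131% ± 1.6e-04 in AS and 0.0333% ± 0.0245 in SAS.

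Both treatments moved many of the same genes the same way. In roots 6269 genes were higher in both, where 2379 would be shared by independent lists, and 4638 were lower in both against 1909. In leaves 3862 were higher in both against 1398, and 3031 lower against 1072. Across genes, which are not independent replicates, the log2 changes of AS and SAS correlated with a Pearson r of 0.774 and a Spearman rho of 0.677 in roots and 0.742 and 0.654 in leaves. The shared control libraries alone gave r of 0.486 in roots and 0.498 in leaves over 10 simulations without any treatment effect. The covariance was 2.08 in roots against 0.0911 simulated, and 0.653 in leaves against 0.0483. The 3 control libraries are too few to split, so part of the overlap counts can come from sharing them.

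The comparison of root and leaf responses asks which genes answered the same treatment differently in each tissue. A peroxidase, Gh_D04G1101, fell in roots, from 22.3 ± 28.0 CPM in CK to 0.665 ± 0.997 in AS and 0.179 ± 0.0632 in SAS, and rose in leaves, from 0.487 ± 0.193 to 16.9 ± 6.57 and 10.01 ± 0.870 (interaction adjusted p = 9.5e-05 for AS and 2.4e-05 for SAS). Fitted to roots alone its log2 change was -5.11 ± 1.29 in AS (adjusted p = 0.0118) and -7.004 ± 1.48 in SAS (adjusted p = 0.00277). The fitted difference, root minus leaf, was -10.19 for AS, but -8.36 without CK root library 1 and -9.59 without AS root library 2 and -12.98 without AS root library 3, and -11.28 for SAS, but -9.46 without CK root library 1. A beta-1,6-N-acetylglucosaminyltransferase gene, Gh_D02G0245, stood at 0.0252 ± 0.0436, 57.9 ± 33.9 and 688 ± 245 CPM in CK, AS and SAS roots and at 0.335 ± 0.156, 1.497 ± 0.375 and 1.96 ± 0.685 in the leaves (interaction adjusted p = 1.8e-07 for SAS), with CK root libraries other than 2 at 0 counts. These levels were scaled over all 18 libraries. For the lists below differences are root minus leaf over the members tested in both tissues, whose number is given, and medians by library totals are those with library totals as the only scaling. Class III peroxidases (35 members) differed by a median log2 of -2.68 for AS (camera adjusted p = 1.7e-13, adjusted p = 0.0165 with an estimated correlation) and -2.45 for SAS (camera adjusted p = 1.7e-08, adjusted p = 0.0684 with an estimated correlation), or -3.28 and -3.11 by library totals. Photosystem and light harvesting genes (45 members) differed by a median log2 of 1.26 for AS (camera adjusted p = 3.0e-06, adjusted p = 0.371 with an estimated correlation) and 2.40 for SAS (camera adjusted p = 1.6e-11, adjusted p = 0.138 with an estimated correlation), or 0.67 and 1.71 by library totals. Compatible solute and stress sugar genes (34 members) differed by a median log2 of 1.75 for AS (camera adjusted p = 3.6e-11, adjusted p = 0.0188 with an estimated correlation) and 1.85 for SAS (camera adjusted p = 1.2e-08, adjusted p = 0.0684 with an estimated correlation), or 1.18 and 1.16 by library totals. Phenylpropanoid genes (64 members) differed by a median log2 of -1.41 for AS (camera adjusted p = 1.2e-09, adjusted p = 0.152 with an estimated correlation) and -1.84 for SAS (camera adjusted p = 4.2e-07, adjusted p = 0.276 with an estimated correlation), or -1.99 and -2.53 by library totals. Alternative oxidases and dehydrogenases (16 members) differed by a median log2 of 0.91 for AS (camera adjusted p = 2.4e-06, adjusted p = 0.0188 with an estimated correlation) and 1.03 for SAS (camera adjusted p = 9.9e-05, adjusted p = 0.0684 with an estimated correlation), or 0.32 and 0.33 by library totals. NAC factors (125 members) differed by a median log2 of 0.75 for AS (camera adjusted p = 2.8e-07, adjusted p = 0.132 with an estimated correlation) and 0.91 for SAS (camera adjusted p = 1.7e-05, adjusted p = 0.206 with an estimated correlation), or 0.17 and 0.21 by library totals.

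Of 35697 genes tested in both tissues, the AS response differed for 12565, 6613 of them more positive in root and 5952 more positive in leaf, and the SAS response differed for 17400, 8799 and 8601. Jasmonate genes (60 members) differed by a median log2 of 1.20 for SAS (camera adjusted p = 5.0e-05, adjusted p = 0.416 with an estimated correlation), or 0.50 by library totals. Across genes, root and leaf log2 changes correlated with r of 0.214 and rho of 0.133 for AS, and 0.348 and 0.320 for SAS. With library totals as the only scaling 16.1% of the AS and 20.4% of the SAS differences were more positive in root, and with limma on log2 FPKM 16.2% and 20.1%, against 52.6% and 50.6%.

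**Figure D3:**
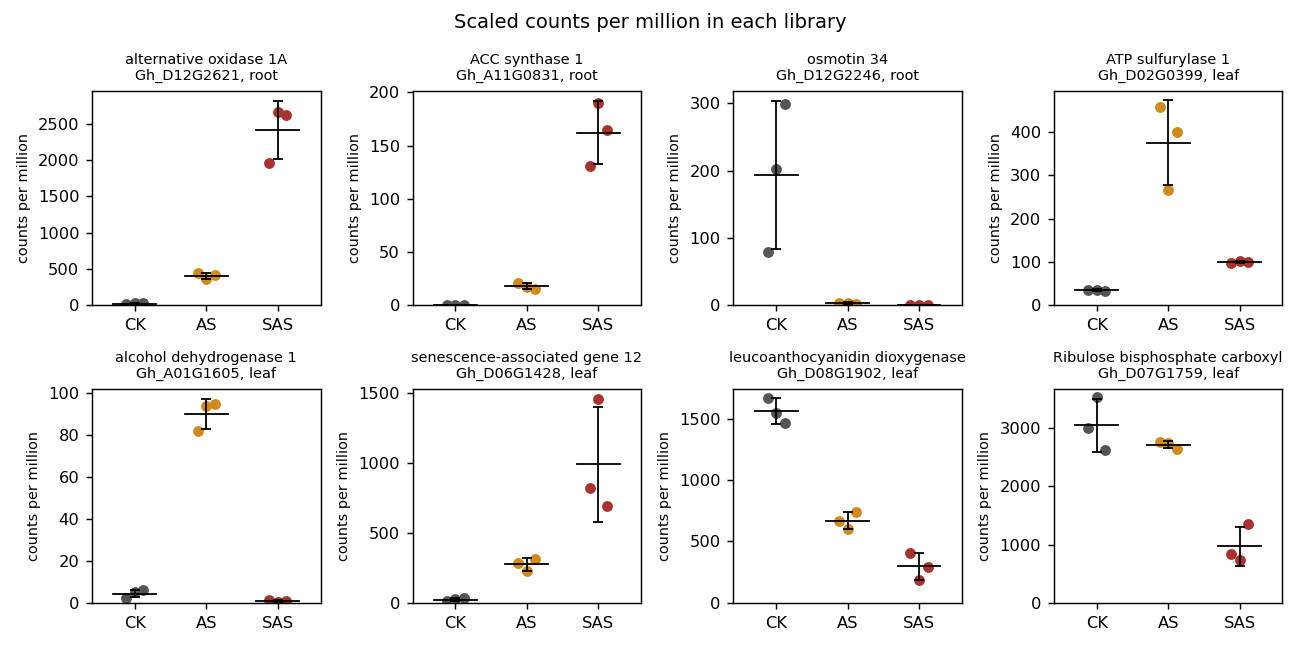
CPM of 8 genes in each library, as points, with the mean as a line and the SD over n = 3 libraries as an error bar, each axis starting at 0. Alternative oxidase 1A rose from a mean of 23.01 in CK roots to 404 in AS and 2414 in SAS roots, and alcohol dehydrogenase 1 stood at 90.1 in AS leaves and 0.912 in SAS leaves.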

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

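The tests of leaf RNA, of scaling and of root hair markers were chosen only after the results were seen. Each result here was picked because its response differed between root and leaf by a test of the interaction term itself.

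The AS response differed between root and leaf for 12565 genes and the SAS response for 17400. Libraries relabelled at random within each tissue gave at most 8973 genes for AS, where the same fit gave 13389 with the real labels, and at most 11646 for SAS, where it gave 16773. The real labels gave the highest of 25 counts per treatment, but draws can keep 1 tissue's effect, so chance stays open.

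Class III peroxidases, lower in most of their changed members in stressed roots (89 tested) and higher in most in stressed leaves (51 tested), differed over the 35 tested in both tissues by a median log2, root minus leaf, of -2.68 for AS (adjusted p = 0.0165 with an estimated correlation) and -2.45 for SAS (adjusted p = 0.0684 with an estimated correlation, so not past the threshold). Scaling between libraries was excluded as the whole cause, since the median nearest to 0 over both treatments and both other scalings was -2.45. A loss of root hair or endodermis cells in stressed roots cannot be told apart from a change within cells. The 7 markers had a median log2 change of -0.297 in SAS roots (quartiles -2.82 and 0.13) and -0.33 in AS roots (quartiles -1.82 and 0.11), too wide a spread to decide, while their share of root counts was 0.0275% ± 0.00164 (SD) in CK, 0.00786% ± 0.00191 in AS and 0.00453% ± 1.4e-04 in SAS. A difference between the tissues in the response itself, which the design names, stays open.

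Photosystem and light harvesting genes, 45 tested in both tissues, differed by a median log2, root minus leaf, of 1.26 for AS and 2.40 for SAS, or 0.67 and 1.71 by library totals, but did not pass with an estimated correlation (adjusted p = 0.371 for AS and adjusted p = 0.138 for SAS). In stressed roots median log2 changes stayed above 0. Library totals took them from 0.75 to 0.27 in AS and from 1.08 to 0.53 in SAS, so scaling was not excluded. In AS roots 111 abundant leaf transcripts gained a median of -0.0478% of their leaf level (quartiles -0.392 to 0.0110), and their whole level there was a median of 0.226%. Photosystem genes gained a median of 0.368% (quartiles -0.132 to 1.82). The quartiles of both sets overlap, and photosystem genes had no minimum leaf level. These percentages are by library totals, which shift AS roots by -0.48 log2, so leaf RNA was not excluded there. In SAS roots 72 such transcripts gained a median of 0.252% (quartiles 0.103 to 1.37), against 0.528% (quartiles 0.0784 to 3.34). The 72 were picked against CK roots alone, so genes SAS raised in roots qualify and leaf RNA stays open. A difference between the tissues in the response itself does too.

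Circadian clock genes differed by a median log2, root minus leaf, of 0.64 for AS (camera adjusted p = 1.2e-05, adjusted p = 0.152 with an estimated correlation), or 0.05 by library totals (all genes -0.60). Cytosolic ribosomal proteins differed by -0.34 for SAS (camera adjusted p = 0.0153, adjusted p = 0.894 with an estimated correlation), or -1.04 by library totals (all genes -0.72). The following genes had the largest fitted differences, and where a group was at 0 counts the fitted value depends on the prior count and is no bound. A protein kinase, Gh_D07G1943, differed by 12.36 for AS, its fold change against CK in root being at least 201 times that in leaf with 0 counts at the floor, and CPM in CK, AS and SAS was 0 ± 0, 10.5 ± 4.90 and 1.499 ± 0.338 in roots and 8.60 ± 0.709, 7.52 ± 0.953 and 4.77 ± 4.09 in leaves. UDP-glucosyl transferase 85A2, Gh_D13G0523, differed by 11.23 (10.64 without AS root library 1) for AS and 15.77 for SAS, its fold change in root being at least 91.9 and 2158 times that in leaf, and CPM in CK, AS and SAS was 0 ± 0, 5.66 ± 3.65 and 87.6 ± 57.1 in roots and 1.80 ± 0.432, 1.85 ± 0.359 and 1.22 ± 0.487 in leaves. A cupredoxin, Gh_D13G0377, differed by -10.81 (-11.65 without AS root library 3) for AS and -14.86 (-15.82 without SAS root library 1) for SAS, its fold change in leaf being at least 87.2 and 1453 times that in root, and CPM in CK, AS and SAS was 11.6 ± 4.68, 1.29 ± 0.985 and 0.946 ± 0.781 in roots and 0 ± 0, 0.453 ± 0.189 and 5.53 ± 1.17 in leaves. A UDP-glycosyltransferase, Gh_A12G2647, differed by -10.59 (-9.96 without AS leaf library 2) for AS, its fold change in leaf being at least 75.2 times that in root, and CPM in CK, AS and SAS was 2.38 ± 0.848, 2.59 ± 0.526 and 21.9 ± 1.52 in roots and 0 ± 0, 3.83 ± 2.35 and 30.2 ± 19.6 in leaves. A pectin lyase-like gene, Gh_D07G1803, differed by -10.85 (-10.26 without SAS leaf library 2) for SAS, its fold change in leaf being at least 90.7 times that in root, and CPM in CK, AS and SAS was 22.01 ± 4.91, 24.5 ± 9.01 and 12.5 ± 4.18 in roots and 0 ± 0, 0.309 ± 0.0764 and 2.41 ± 1.42 in leaves. A peroxidase, Gh_D04G1101, differed by -10.19 (-8.36 without CK root library 1, -9.59 without AS root library 2, -12.98 without AS root library 3) for AS and -11.28 (-9.46 without CK root library 1) for SAS. A glucosaminyltransferase, Gh_D02G0245, differed by 12.01 for SAS, with CK root libraries other than 2 at 0 counts.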

How the results depend on the processing

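The DESeq2 fits, library totals as the only scaling, the fixed replicate term and the estimated correlation for annotation terms were chosen only after results were seen, and the other alternatives beforehand. The count of changed genes stayed within 1.5 times its main value except as follows. AS against CK in leaves gave 4149 genes in place of 9268 with all 18 libraries in a single fit, and SAS against AS in leaves 8934 in place of 17919, and the cause was not tested. Leaving out one library took the AS leaf count to between 4520 and 8868, with 5633, 4639 and 6005 without CK leaf library 1, 2 or 3 and 4520 and 4830 without AS leaf library 1 or 3. The SAS interaction fell to 11069 genes with an FPKM minimum of 5, which tests fewer genes. DESeq2 gave 16986, 23610, 17516, 11954, 25076 and 19841 genes for AS, SAS and SAS against AS in roots and then in leaves, and a replicate block 13039, 21070, 13930, 7141, 22307 and 15858. Replicate numbers do not pair the libraries, since 0 of 15 pairs of groups had same-number correlations all over 0.1, and 2 of 18 libraries matched best with their own number. An estimated correlation left 1, 3, 0, 0, 0 and 0 gene lists past camera in place of 16, 18, 16, 15, 23 and 21, with 4, 9, 7, 7, 6 and 4 at an unadjusted p under 0.05. The annotation terms past camera fell to 0, 0, 0, 0, 0 and 0 from 155, 175, 231, 323, 307 and 394, with 60, 75, 93, 151, 43 and 106 GO and 8, 6, 21, 10, 3 and 9 KEGG terms at an unadjusted p under 0.05, and the cause was not tested. The AS and SAS correlation across genes in roots was 0.809 with an FPKM minimum of 5 and 0.739 to 0.796 with one library left out, against 0.774. In leaves it was 0.698 and 0.716 with limma at pseudocounts of 1 and 0.1 and 0.698 to 0.772 with one library left out, against 0.742, and the cause was not tested. Of 372 pairs of named gene and comparison, 346 stayed past the threshold under every alternative, 26 were lost under at least 1, and 0 reversed, and 92 moved by over 1.5 times without a single library. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. In edgeR fits of the 6 libraries alone the real split called 15189, 21951, 14310, 13002, 22034 and 14496 genes in the same order, and the highest of the other splits 0 in each, with at most 1271, 522, 1672, 2125, 669 and 1719 genes at an unadjusted p under 0.05. Depth limits what can be called, since a gene at 0 counts in a group gives only a bound on its fold.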

Other observations

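The estimated correlation for annotation terms and the test of root RNA were chosen only after the results were seen. Annotation terms gave further gene groups beyond the fixed lists. In AS against CK roots 80 of 134 genes annotated to the response to hydrogen peroxide were higher and 10 lower (camera adjusted p = 3.3e-21), and 18 of 32 genes for UDP-glycosyltransferases, which attach sugars to small molecules, were higher and 0 lower (camera adjusted p = 3.4e-06). In the same roots 3 of 43 genes for proteins of the endoplasmic reticulum lumen were higher and 30 lower (camera adjusted p = 2.3e-07), and 0 of 29 genes of the oligosaccharyltransferase complex, which attaches sugar chains to new proteins, were higher and 18 lower (camera adjusted p = 9.2e-05). An estimated correlation gave adjusted p = 0.908 for each of them. In AS against CK leaves 50 of 119 genes for the processing of ribosomal RNA were higher and 0 lower (camera adjusted p = 1.8e-09), 1 of 22 genes for cinnamic acid synthesis was higher and 15 lower (camera adjusted p = 1.1e-17), and 2 of 24 genes for pectate lyases were higher and 13 lower (camera adjusted p = 2.5e-08). An estimated correlation gave adjusted p = 0.461 for each of them.

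Both treatments differed in other groups too. In SAS against AS roots 211 of 335 genes annotated to the response to chitin, a fungal wall polymer, were higher and 21 lower (camera adjusted p = 6.8e-15), 19 of 29 genes for sulfotransferases were higher and 1 lower (camera adjusted p = 8.5e-06), and 0 of 20 genes for 1,3-beta-glucan synthases, which make callose, were higher and 14 lower (camera adjusted p = 4.5e-04). An estimated correlation gave adjusted p = 0.750 to 0.765 for these terms. In SAS against AS leaves 22 of 37 genes for calcium-transporting ATPases were higher and 0 lower (camera adjusted p = 4.5e-07), and 11 of 15 genes for inhibitors of serine proteases were higher and 0 lower (camera adjusted p = 2.0e-05). An estimated correlation gave adjusted p = 0.611 for each of them.

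Genes that CK roots expressed at least 10 times above CK leaves were often higher in SAS leaves: of 1264 such genes 940 were higher and 42 lower than in CK leaves, or 74.4% higher against 27.2% of all genes. The CK leaf libraries served both to pick these genes and as the control, which alone favours higher values in treated leaves, and in AS leaves, set against the same controls, 388 were higher and 21 lower. Root markers as first written (63 genes) passed upward in SAS leaves, but the revised 3 were too few to test. Root RNA carried into the SAS leaf libraries was examined with 298 transcripts that were abundant in SAS roots and nearly missing from CK leaves. They gained a median of 2.03% of their root level (quartiles 0.573 to 5.30), against 7.49% for all 1264 genes, whether higher or not (quartiles 1.84 to 23.3). Their whole level in SAS leaves was a median of 2.64% of the root level (quartiles 0.995 to 6.31). Both sets share 194 genes, and their quartiles overlap. As a hypothesis, part of these genes may have risen in leaf cells themselves, which no test here decided.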
